A study of Mus musculus with 19 samples.

How the data were processed

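The data are gene tables from 19 mouse RNA sequencing libraries. Per the labels, 9 came from snap-frozen spinal cords of miR-146a knockout animals, 4 from cords of wild-type animals, 3 from embryonic stem cell derived motor neurons given a locked nucleic acid (LNA) against miR-146a and 3 from motor neurons given a control LNA. Per the submitters' design notes, ribosomal RNA was removed by RNase H, RNA fragments were reverse transcribed from random hexamers, and paired ends of 150 bases were sequenced on a NovaSeq X Plus. Per the same notes, reads were aligned with STAR to the primary assembly of Ensembl release 101, and featureCounts counted reads that aligned uniquely and fell unambiguously into a gene. Transcripts of Rn7sk took 0.5176% to 1.245% of counts in cords and 0.0001% to 0.0003% in cultures. Protein-coding genes took 94.0% to 96.5% in cords and 97.8% to 98.3% in cultures. Cord and culture libraries thus differ in RNA content, and the notes on library preparation may not hold for both alike, which was not tested. The strand setting of the counting and the handling of duplicates are not given in the sources used here. Overlapping and antisense genes, and near-identical copies such as the haemoglobin genes, histone genes and Ccl family, are therefore uncertain, because unique alignment drops reads that copies share and an unstated strand setting leaves antisense partners apart or merged.

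Each table lists 55487 genes. The count column holds the whole-number counts that the authors deposited, and every test used it. The CPM column deposited by the authors scales the counts by their sum, checked in every library against the same calculation. The FPKM column deposited by the authors, which also divides by gene length, and the TPM column deposited by the authors, which rescales such values to a fixed sum per library, were read for the unit check and used in no test. Gene symbols, gene types and transcript sequences came from GENCODE M21, an annotation of the GRCm38 build, whose start and end positions matched those in the tables for 99.4% of matched genes. A symbol was found for 55141 genes (99.4%), and 99.93% of matched genes lay on the same chromosome and strand. Coordinates are 1-based, on GRCm38.

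Libraries were grouped by genotype label or LNA label alone. Replicate numbers of cords follow accession order and only name libraries, while those of the cultures come from the labels. Total counts ran from 28163289 to 39577247 in cords and from 40647549 to 65471742 in cultures, so 3 counts amount to 0.0758 to 0.1065 CPM in cords and 0.0458 to 0.0738 CPM in cultures. These limits cover counting error only. No pair of libraries of a group matched within sampling noise, the smallest chi-square per degree of freedom being 6.42.

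The main test was the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, fitted to the 2 groups of each comparison after its default filter on low counts and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and the test's F value. Normalised CPM means TMM-scaled CPM. The difference between the knockout effect and the LNA effect was an interaction term in 1 edgeR fit over all 19 libraries. DESeq2 1.42.0, limma 3.58.1 with voom quality weights, sva 3.50.0 with 2 surrogate variables, other scalings, other filters, a fold threshold of 1.5, a replicate block in the cultures and leaving out each library in turn were alternatives, listed before the data were examined. The fits without both cord libraries that stand apart, the fits on libraries with Xist above 100 CPM and the permutation of list scores were chosen after seeing the data.

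Before the data were examined, 41 gene lists were fixed for cell types and pathways of the spinal cord and motor neuron. Lists with at least 5 tested members were compared with all other genes by camera of limma with a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over 39 lists in cords and 37 in cultures. Left out were pluripotency genes (4 tested) and sex-linked genes (1 tested) in cords, and red blood cell genes (1 tested), neutrophil and monocyte genes (3 tested), lymphocyte genes (3 tested) and sex-linked genes (0 tested) in cultures. The same test with an estimated correlation and the fry test were alternatives, and an exact two-sided permutation of list scores was added. A list score is the mean over members of log2 CPM minus the mean of all libraries of that material. With 3 against 3 libraries the smallest possible exact p is 0.1. Camera with the preset correlation called a median of 14 lists in 100 drawn splits of the cord libraries. Its calls of named lists over all cord libraries are therefore given with the estimated-correlation value. Calls gained or lost on leaving out 1 library are with the preset correlation.

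Genes to be named were fixed by rule: the 12 highest and 12 lowest calls with at least 1 normalised CPM in the higher group; where under 6 genes passed in a direction, the 3 with the smallest p; Irak1, Traf6 and Sod1; up to 4 members with the smallest p from each list discussed, of which 2 or 3 are given; and the 5 genes with the smallest p for the difference and for agreement. Some genes that the rule picks are not reported here, and no others were named in their place. In choosing by fold or by p over all genes, gene models without a proper name, pseudogenes and members of the fixed sex-linked list were passed over; other genes on chromosome X were kept. List members were not screened in this way, and Clec7a among them is annotated as a polymorphic pseudogene. Which lists are discussed was chosen after the list results were seen. Pttg1, Col23a1, Il18rap, Arc, Lpp, Acta1 and Col1a1 fall outside the rule and were chosen after their values were seen.

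Matches to the miR-146a-5p seed, AGTTCTC, were sought in the longest annotated 3' UTR of 20992 genes and found in 2344. Fold changes of genes with and without a site were compared by camera, with 200 other 7-base words as controls. The same words were run through the linear model with 3' UTR length, A+U share and expression, a test chosen after seeing the data. Genes within 5 Mb of Mir146 were compared with all others by Fisher's exact test. Each step was tested on simulated counts with known changes. These counts took the means, dispersions and library sizes of each comparison, with genes independent and the same dispersion in both groups. For the cords, edgeR recovered 48% of genes changed 1.5-fold and 70% of those changed 2-fold. Of its calls 1.89% were false, against 18.7% for DESeq2. For the cultures, edgeR recovered 72% and 90% at these folds, with 11.7% of its calls false, and for the interaction 12.6% and 58.2%, with 2.13% false. In simulated cords camera called 0 lists without a shift, against a median of 14 in splits of the real cords. These rates therefore need not hold in the real cords.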

Results

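RNA was profiled in 2 mouse materials in which miR-146a was lost or inhibited. miR-146a is a microRNA known to restrain NF-kB signalling, in part through Irak1 and Traf6, and the series is about its part in the degeneration of motor neurons. Spinal cords gave 9 libraries labelled miR-146a knockout and 4 labelled wild type. Motor neurons, differentiated with retinoic acid and a Smoothened agonist from the embryonic stem cell line RW.4, gave 3 libraries after transfection of 10 nM miR-146a LNA for 72 h and 3 after a control LNA. An LNA is a stabilised oligonucleotide that binds and blocks a microRNA. Total counts were lowest in the library labelled knockout replicate 9 (28163289) and highest among cords in knockout replicate 7 (39577247), and the cultures held 40647549 to 65471742. Mitochondrial transcripts took 1.61% to 1.99% of counts in cords and 0.454% to 0.590% in cultures. The labels give no sex, age, litter or batch and do not say that libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries.

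The targeted gene could not be read in these libraries. Mir146, the miR-146a precursor on chromosome 11 from 43374397 to 43374461 (GRCm38), had 1 count in the 9 knockout libraries together and 0 in the 4 wild-type libraries, where 3 counts over a group are 0.0094 and 0.0221 CPM. Both culture groups had 0 counts, below 0.018 CPM after the miR-146a LNA and 0.0178 CPM after the control LNA. The precursor therefore checks neither the genotype labels nor the LNA.

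A neighbour of Mir146 did separate the genotypes, except in 1 library. Pttg1 (ENSMUSG00000020415, chromosome 11, 43420250 to 43426251, minus strand) encodes securin, the inhibitor of sister chromatid separation, and lies 45.8 kb from the precursor. It stood at 14.9 to 17.4 normalised CPM in the 4 wild-type cords and at 1.06 to 1.81 in knockout replicates 1 to 8. The library labelled knockout replicate 9 had 13.04 normalised CPM, from 383 counts against 40 to 65 in the other knockout libraries. Over all 9 against 4 libraries the log2 fold change was −2.57 (SE 0.61, adjusted p = 0.292 with edgeR, 2.95e-14 with DESeq2 and 9.24e-09 with limma), and without that library it was −3.45 (SE 0.12, adjusted p = 1.49e-09 with edgeR). DESeq2 was set to replace outlying counts among the knockout cords, so its value need not rest on the count in the library labelled knockout replicate 9. The same library had Sod1, the superoxide dismutase gene mutated in some familial motor neuron disease, at 1947 normalised CPM, 8.05 times the mean of the other 8 knockout libraries. At Pttg1 it goes against its label, so it is named here as the library labelled knockout replicate 9, was kept in its labelled group, and counts of called genes and the scores of 9 lists are also given without it.

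**Figure D1:**
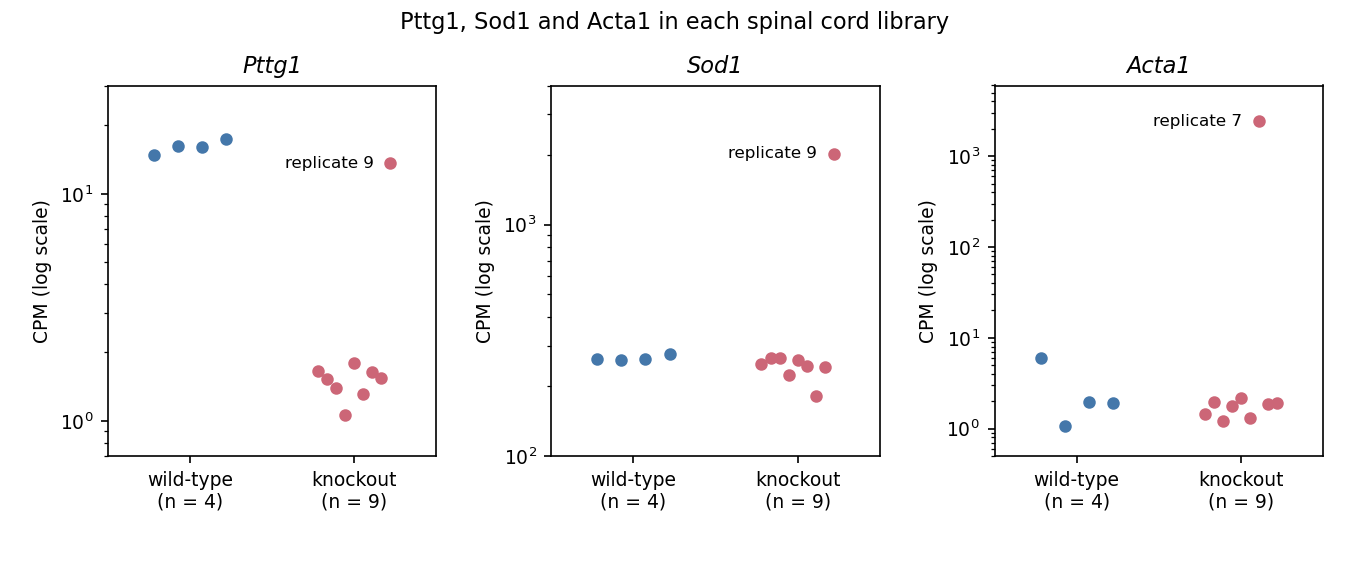
Points show the CPM (log axis) of Pttg1, Sod1 and Acta1 in each of the 4 wild-type and 9 knockout spinal cord libraries. The library labelled knockout replicate 9 has 13.6 CPM of Pttg1 and 2031 CPM of Sod1, and Acta1 reaches 2436 CPM in knockout replicate 7.

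The cord comparison asks which genes differ when miR-146a is absent from the spinal cord. Genes of microglial activation, reactive astrocytes, interferon signalling, complement and NF-kB were higher in the knockout libraries as lists by camera with a preset correlation, but not by its other form (adjusted p = 0.339 with an estimated correlation for each of the 5 lists). The spread between knockout libraries was wide, and no single gene passed the adjusted threshold with edgeR. Clec7a, a fungal pattern receptor of activated microglia, stood at 9.47 ± 8.36 normalised CPM (SD, n = 9) against 1.19 ± 0.354 (SD, n = 4), and C4b, complement component C4, at 571 ± 343 against 159 ± 12.1. Ttr, the thyroxine carrier made by choroid plexus, had the smallest p of all genes, at 0.448 ± 0.274 against 3.38 ± 1.55, and lay below every wild-type library in 9 of 9 knockout libraries. The neurofilament gene Nefm, abundant in large motor axons, stood at 1746 ± 196 against 2258 ± 290.

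edgeR called 0 of 22174 tested genes. At an unadjusted p below 0.05 there were 3177 genes. DESeq2 called 348 genes, 289 higher and 59 lower in knockout cords, and limma with quality weights called 3, which were Il18rap, Pttg1 and Ttr. Without the library labelled knockout replicate 9, edgeR called 2 genes, Pttg1 and Col23a1 (a transmembrane collagen, log2 0.52, adjusted p = 0.0188), both on chromosome 11, with 3350 genes at an unadjusted p below 0.05. Without knockout replicate 7 it called Alas2 and Slc4a1, and without knockout replicate 2 it called Arc (log2 −0.59, adjusted p = 0.0463), an activity-induced synaptic gene.

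Among single genes, those with the smallest p on the higher side were Alas2, Slc4a1 and Dchs1. Alas2 (chromosome X, 150547375 to 150570638), the first enzyme of haem synthesis in erythroid cells, had a log2 fold change of 3.13 (SE 0.53, adjusted p = 0.292 with edgeR, 6.14e-07 with DESeq2), from 8.54 ± 5.93 against 0.971 ± 0.281 normalised CPM. Slc4a1, the anion exchanger of red cell membranes, had 4.33 (SE 0.80), and Dchs1, a protocadherin of planar cell polarity, had 0.45 (SE 0.09) from 39.8 ± 4.37 against 29.1 ± 2.86. All 3 were above every wild-type library in 9 of 9 knockout libraries. On the lower side Ttr (chromosome 18, 20665280 to 20674321) had −2.91 (SE 0.43, adjusted p = 0.179 with edgeR), followed by Tyro3, a receptor kinase for phosphatidylserine ligands, at −0.29 (SE 0.06), and Apln, the apelin peptide of endothelium, at −0.72 (SE 0.14), both with an adjusted p of 0.292 with edgeR. With DESeq2 the adjusted p was 1.24e-06 for Slc4a1, 0.00272 for Dchs1, 8.98e-07 for Ttr, 0.00332 for Tyro3 and 0.00199 for Apln.

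Genes of microglial activation and astrocyte reactivity were higher in most but not all knockout libraries. Of 26 disease-associated microglia genes, 25 had a positive fold change, with a median log2 of 1.48, and 17 were higher when adjusted over the list alone, while 10 passed over all genes with DESeq2. Camera called the list (adjusted p = 7.2e-12), with adjusted p = 0.339 with an estimated correlation. Besides Clec7a (2.99, SE 0.81), Ch25h, which makes 25-hydroxycholesterol, had 3.295 (SE 0.96) and the integrin Itgax 3.89 (SE 1.13). The list score was 0.448 ± 1.10 (SD, n = 9) in knockout and −1.01 ± 0.150 (SD, n = 4) in wild-type libraries, a difference of 1.46 with an exact permutation p of 0.028 (0.127 adjusted over the lists), and knockout replicate 2 (−1.40) lay below every wild-type library. Of 29 reactive astrocyte genes, 28 had a positive fold change, with a median of 1.47, and 24 were higher when adjusted over the list alone (camera adjusted p = 3.52e-13, adjusted p = 0.339 with an estimated correlation). Examples were the chemokine Cxcl10 (2.27, SE 0.58), the oncostatin M receptor Osmr (1.73, SE 0.47) and the bile salt transporter family member Slc10a6, which had 0 counts in wild-type and 80 counts in knockout libraries, at least 11.4-fold higher against a floor of 3 counts over the group.

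**Figure D2:**
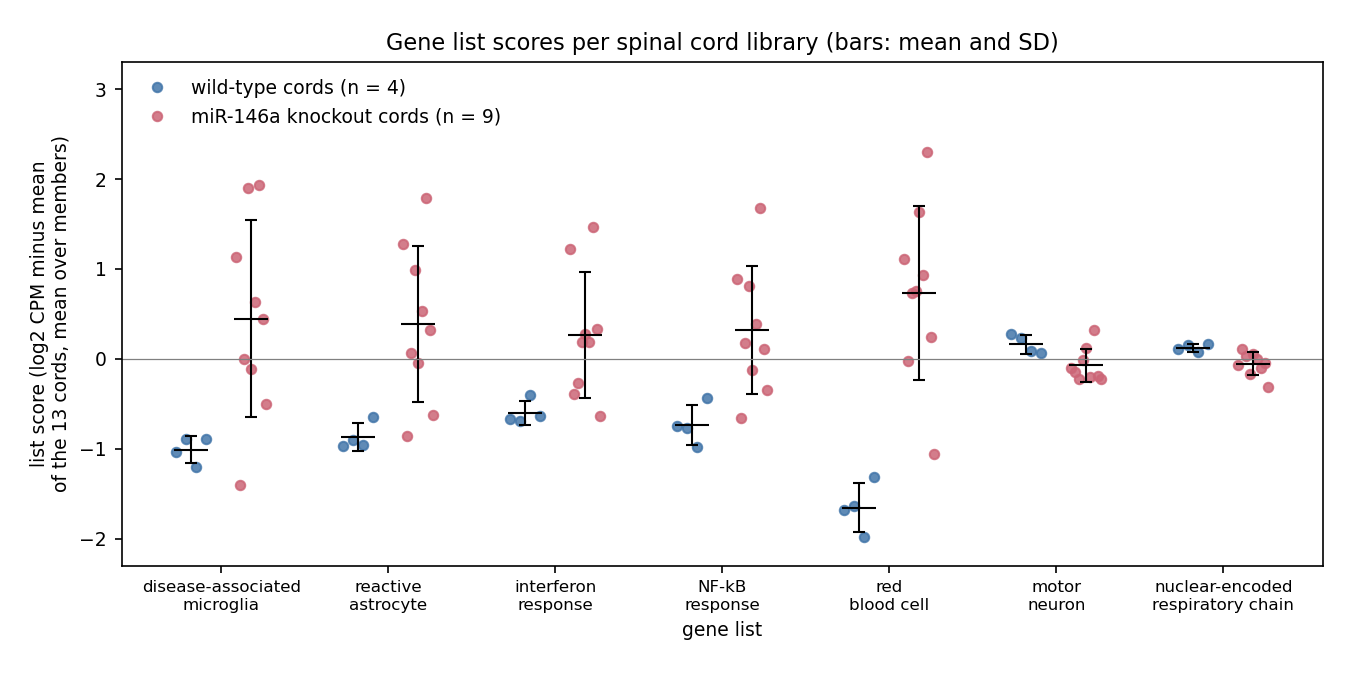
Points show gene list scores (mean over members of log2 CPM minus the mean of the 13 cords) in each spinal cord library, with bars for the mean and SD of 4 wild-type and 9 knockout libraries. The disease-associated microglia score spreads from −1.40 in knockout replicate 2 to 1.93 in knockout replicate 7, while wild-type libraries average −1.01.

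Immune signalling lists showed the same sign. All 33 interferon response genes had positive fold changes, with a median of 1.05, and 16 were higher when adjusted over the list alone (camera adjusted p = 6.53e-14, adjusted p = 0.339 with an estimated correlation). Mx1, an antiviral dynamin-like GTPase, had 1.98 (SE 0.55) and the immunity-related GTPase Irgm1 0.69 (SE 0.21). All 26 genes of complement and antigen presentation were positive, with a median of 1.24 and 17 higher when adjusted over the list alone (camera adjusted p = 8.32e-12, adjusted p = 0.339 with an estimated correlation). Nlrc5, the transactivator of MHC class I genes, had 1.38 (SE 0.31) and C4b 1.85 (SE 0.53). Of 27 NF-kB response genes, the pathway miR-146a is known to restrain, 25 were positive, with a median of 0.93 and 12 higher when adjusted over the list alone (camera adjusted p = 1.28e-10, adjusted p = 0.339 with an estimated correlation). The chemokines Ccl2 (5.63, SE 1.26), Ccl3 (3.28, SE 0.85) and Ccl5 (1.74, SE 0.52) led it. Their means were 1.29, 2.80 and 1.73 normalised CPM in knockout cords, against 0.0235, 0.284 and 0.515 in wild-type cords. The wild-type mean of Ccl2 lies near 0.0221 CPM, which is 3 counts over that group, so the size of its fold change is uncertain. Leaving out the library labelled knockout replicate 9 moved the difference of list scores from 0.863 to 0.976 for interferon, 1.01 to 1.15 for complement, 1.06 to 1.14 for NF-kB, 1.46 to 1.58 for microglia and 1.25 to 1.38 for astrocytes. It moved that of reported targets from 0.326 to 0.361, of the respiratory chain from −0.182 to −0.15, of cholesterol synthesis from −0.265 to −0.269 and of motor neurons from −0.236 to −0.217. The smallest adjusted p of any list without that library was 0.127 with an estimated correlation.

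The list of reported miR-146a targets had a positive median in knockout cords. Of 21 tested, 15 had a positive fold change, with a median of 0.16, and 0 passed with edgeR when adjusted over the list alone, against 5 at an unadjusted p below 0.05 and 2 over all genes with DESeq2. Camera called the list (adjusted p = 0.00521), with adjusted p = 0.462 with an estimated correlation. Its leading members were Fas, a death receptor (1.08, SE 0.31), Ptgs2, cyclooxygenase 2 (2.22, SE 0.70), and the endotoxin receptor Tlr4 (1.48, SE 0.55). The signalling mediators most often named as its targets moved little, Irak1 by 0.13 (SE 0.08, adjusted p = 0.47) and Traf6 by 0.11 (SE 0.09, adjusted p = 0.554). Sod1 (chromosome 16, 90220754 to 90226329) had 0.68 (SE 0.66, adjusted p = 0.649), with 431 ± 569 against 269 ± 6.54 normalised CPM, with 1 of 9 knockout libraries above every wild-type library and 6 of 9 below every one. Without the library labelled knockout replicate 9 its fold change was −0.15.

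Lists of energy metabolism, sterol synthesis and motor neurons had negative medians in knockout cords, and camera called them with the preset correlation (adjusted p = 0.339 with an estimated correlation for each). All 44 nuclear-encoded respiratory chain genes had negative fold changes, with a median of −0.18. edgeR called 0 of them when adjusted over the list alone, against 29 lower at an unadjusted p below 0.05 and 0 over all genes with DESeq2 (camera adjusted p = 1.57e-16, adjusted p = 0.339 with an estimated correlation). Cox6c, a subunit of cytochrome c oxidase, had −0.21 (SE 0.06) and Cyc1, cytochrome c1, −0.22 (SE 0.07). All 20 cholesterol synthesis genes were negative, with a median of −0.28 and 0 called by edgeR when adjusted over the list alone, against 11 at an unadjusted p below 0.05 and 0 with DESeq2 (camera adjusted p = 2.29e-08, adjusted p = 0.339 with an estimated correlation). Squalene synthase Fdft1 had −0.33 (SE 0.10) and the desaturase Sc5d −0.22 (SE 0.07). Of 24 motor neuron genes, 16 were negative, with a median of −0.30, and 6 were lower when adjusted over the list alone (camera adjusted p = 0.000237, adjusted p = 0.339 with an estimated correlation). Chodl, a marker of fast motor neurons, had −1.01 (SE 0.26), and the neurofilaments Nefm and Nefl −0.37 (SE 0.10) and −0.36 (SE 0.10).

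Markers of other cells moved with the groups above. Red blood cell genes had a median of 2.97, and 6 of 7 were higher when adjusted over the list alone (camera adjusted p = 1.27e-08, adjusted p = 0.339 with an estimated correlation, exact permutation p of the score 0.0014, or 0.0546 adjusted over the lists). Beta globin Hbb-bs stood at 76.2 ± 54.7 against 9.68 ± 2.95 normalised CPM. Neutrophil and monocyte genes had a median of 3.51, with 2 of 10 higher when adjusted over the list alone (camera adjusted p = 0.000171, adjusted p = 0.462 with an estimated correlation). Skeletal muscle genes were not called (adjusted p = 0.356), but Acta1, the actin of skeletal muscle, reached 2436 CPM in knockout replicate 7, against at most 5.97 CPM in any other cord, and Col1a1, type I collagen, reached 1092 CPM there. Knockout replicate 7 also had the highest value of Alas2, Slc4a1, Itgax, Ccl2, Mx1 and Tlr4 among cords. Without both it and the library labelled knockout replicate 9, edgeR called 8 genes, which were Il1r1, the interleukin 1 receptor (1.71), Lpp (0.50), Alas2, Slc4a1, Dchs1, Pttg1, Col23a1 and Ttr.

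The culture comparison asks what 72 h of miR-146a inhibition changes in motor neurons. In the fixed lists, 11 of 33 synapse genes, 12 of 29 axon guidance genes, 4 of 18 spinal interneuron genes and 9 of 19 cholesterol synthesis genes fell. Camera called these 4 lists with the preset correlation (adjusted p = 0.399, 0.559, 0.399 and 0.439 with an estimated correlation). Cacna2d3 (chromosome 14, 28904943 to 29721864), an auxiliary subunit of voltage-gated calcium channels, fell from 37.9 ± 2.21 to 15.9 ± 1.38 normalised CPM (SD, n = 3 each; log2 −1.25, SE 0.09, adjusted p = 4.61e-07). Mfhas1, a leucine-rich repeat GTPase, fell from 138 ± 3.58 to 77.7 ± 3.93, and Emc1, a subunit of the membrane insertion complex of the endoplasmic reticulum, rose from 72.2 ± 4.80 to 129 ± 4.54. Chodl, the fast motor neuron marker, rose from 1.14 ± 0.255 to 3.86 ± 0.264 (log2 1.75, SE 0.23, adjusted p = 8.59e-05).

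edgeR called 1635 of 19099 tested genes, 458 higher and 1177 lower, or 72.0% lower. Scaling by library size alone called 1572, of which 52.9% were lower, with a median log2 fold change over all genes of 0.053 against 0.008. With a fold threshold of 1.5, 388 genes passed, of which 222 were higher and 166 lower, or 42.8% lower. The count was 778 without control replicate 2, with 172 higher and 606 lower, and 1059 without control replicate 1, with 255 higher and 804 lower. The number of higher genes was also 294 without LNA replicate 1 and 238 without control replicate 3.

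The largest increases were in genes at a few CPM. Gsta4 (chromosome 9, 78182774 to 78209349), a glutathione transferase that clears lipid aldehydes, rose from 0.508 ± 0.0918 to 2.09 ± 0.362 (log2 2.03, SE 0.29, adjusted p = 0.000245). The ubiquitin ligases Rnf135 (1.86, SE 0.36) and Trim6 (1.74, SE 0.35), both of antiviral signalling, the myosin light chain Myl9 (1.73, SE 0.30), the aminopeptidase-like Npepl1 (1.61, SE 0.24) and the inflammasome sensor Nlrp6 (1.44, SE 0.26) rose too. Angptl4, an inhibitor of lipoprotein lipase, rose by 1.48 (SE 0.20), from 2.00 ± 0.419 to 5.57 ± 0.513. The oligodendrocyte lineage gene Bcas1 (1.66, SE 0.37), Tmem37 (1.60, SE 0.35), the histone gene Hist1h4i (1.51, SE 0.31) and the pantetheinase Vnn1 (1.43, SE 0.42, adjusted p = 0.0445) completed the 12.

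Among the 12 largest decreases, the nicotinic receptor subunit Chrna2, found in Renshaw cells, fell by 1.71 on the log2 scale (SE 0.37), the ghrelin receptor Ghsr by 1.61 (SE 0.40), the ferlin Fer1l6 by 1.55 (SE 0.31) and Sytl5, a Rab27 effector, by 1.37 (SE 0.36). Synpr, a synaptic vesicle protein, fell from 9.84 ± 0.502 to 3.99 ± 0.834 (log2 −1.29, SE 0.16, adjusted p = 5.2e-05). The glycine transporter of inhibitory neurons Slc6a5 (−1.19, SE 0.31), the synaptic organiser Cbln4 (−1.16, SE 0.34), the collagen Col25a1 (−1.25, SE 0.37), needed by motor axons to enter muscle, the myosin kinase Mylk (−1.27, SE 0.23), Aff2 (−1.21, SE 0.33) and Zfp804b (−1.08, SE 0.18) fell as well.

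Neuronal lists leaned down. Genes of long genomic span also fell in general, 779 falling and 53 rising among the 3603 longest. Camera does not match lists by span, and whether these lists fell beyond that trend was not tested. Of 33 synapse genes, 11 fell over all genes tested and 14 fell when adjusted over the list alone (median −0.16, camera adjusted p = 6.61e-06, adjusted p = 0.399 with an estimated correlation), among them the adhesion molecule Nlgn1 (−0.51, SE 0.06) and the active zone scaffold Rims1 (−0.53, SE 0.06). Of 29 axon guidance genes, 12 fell, and adjusted over the list alone 17 fell and 4 rose (median −0.20, camera adjusted p = 6.69e-05, adjusted p = 0.559 with an estimated correlation), with the netrin receptor Dcc (−0.69, SE 0.08), the semaphorin receptor Nrp2 (−0.47, SE 0.06) and the Slit receptor Robo1 (−0.46, SE 0.06). Of 18 spinal interneuron genes, 4 fell, and adjusted over the list alone 10 fell and 1 rose (median −0.61, camera adjusted p = 0.00116, adjusted p = 0.399 with an estimated correlation). These included Gad1 (−1.07, SE 0.17) and Gad2 (−0.44, SE 0.10), which make GABA, and the nitric oxide synthase Nos1 (−0.58, SE 0.16). Motor neuron genes went both ways, with 5 higher and 2 lower of 24 both over all genes and adjusted over the list alone, and the list was not called (median 0.05, adjusted p = 0.185). The homeodomain factor Isl1 rose (0.31, SE 0.06) and the neurotrophic receptor Ret fell (−0.30, SE 0.05).

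**Figure D3:**
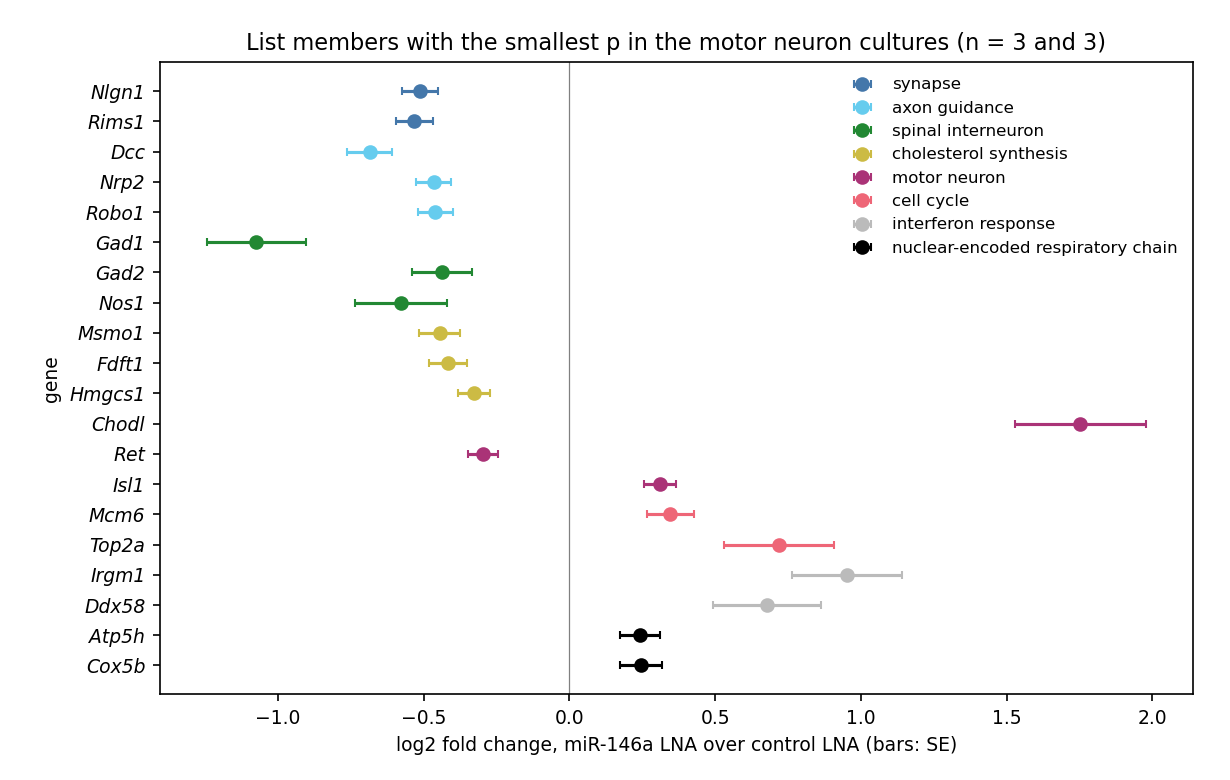
Points show the log2 fold change (miR-146a LNA over control LNA, n = 3 each) of the list members with the smallest p, grouped by list, with bars for the standard error. Synapse, axon guidance, interneuron and cholesterol synthesis members lie below 0, down to −1.07 for Gad1, and Chodl lies at 1.75.

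Metabolic and proliferation lists moved as well. Of 19 cholesterol synthesis genes, 9 fell and 13 fell when adjusted over the list alone (median −0.25, camera adjusted p = 2.04e-05, adjusted p = 0.439 with an estimated correlation), including Msmo1 (−0.45, SE 0.07), Fdft1 (−0.42, SE 0.07) and Hmgcs1 (−0.33, SE 0.05). All 44 nuclear-encoded respiratory chain genes had positive fold changes (median 0.17, camera adjusted p = 2.04e-05, adjusted p = 0.559 with an estimated correlation). The difference of list scores was 0.17 and fell to 0.0789 without LNA replicate 3. Of these genes, Atp5h (0.24, SE 0.07) and Cox5b (0.25, SE 0.07) passed over all genes, and edgeR called 0 when adjusted over the list alone, against 13 at an unadjusted p below 0.05 and 6 with DESeq2. Of 24 cell cycle genes, 4 rose and 6 rose when adjusted over the list alone (median 0.44, camera adjusted p = 2.04e-05, adjusted p = 0.449 with an estimated correlation), including topoisomerase Top2a (0.72, SE 0.19) and the replication helicase subunit Mcm6 (0.35, SE 0.08). Of 20 interferon response genes, 3 rose and 5 rose when adjusted over the list alone (median 0.37, camera adjusted p = 0.000286, adjusted p = 0.449 with an estimated correlation), among them Irgm1 (0.95, SE 0.19) and the RNA sensor Ddx58 (0.68, SE 0.18). The difference of list scores went from 0.454 to 0.171 without LNA replicate 1 and 0.295 without control replicate 2 for interferon response, and from 0.393 to 0.249 without LNA replicate 1 for the cell cycle. Atp5h, Cox5b, Top2a, Mcm6 and Ddx58 each lost the call in at least 1 fit that left out 1 library.

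Reported targets of miR-146a did not rise in the cultures. Of 19, 1 fell over all genes and 2 fell when adjusted over the list alone, and the list was not called (median −0.05, mean 0.00, adjusted p = 0.631). The splicing factor Nova1 fell (−0.23, SE 0.05), and the retinoic acid receptor Rarb had −0.42 (SE 0.13, adjusted p = 0.0547). Traf6 had −0.05 (SE 0.07, adjusted p = 0.729), Irak1 0.13 (SE 0.07, adjusted p = 0.264) and Sod1 0.24 (SE 0.08, adjusted p = 0.0843). Pttg1 had 0.94 (SE 0.34, adjusted p = 0.104), at 1.19 ± 0.163 against 0.619 ± 0.237 normalised CPM.

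Whether knockout cords and LNA-treated cultures differ in their response was tested by an interaction. Its fit shares dispersions between both materials, so its standard errors can lie below those of the culture fit (for Gsta4, 0.19 against 0.29). The effects differed for 423 of 24152 genes, with 3430 at an unadjusted p below 0.05, and DESeq2 called 892. The smallest p values belonged to Htr1a, Gsta4, Mfhas1, Sorcs2 and Emc1, each of which had changed in the cultures. Htr1a, a serotonin receptor, had 0 counts after the miR-146a LNA and 18 to 29 counts in each control library, at least 22.7-fold lower against a floor of 3 counts over the group. The knockout effect minus the LNA effect was −2.13 (SE 0.19) for Gsta4, 0.87 (SE 0.08) for Mfhas1, 1.00 (SE 0.10) for the sortilin-family receptor Sorcs2, which fell by 0.93 on the log2 scale in the cultures, and −0.88 (SE 0.09) for Emc1. Chodl had −2.74 (SE 0.43, adjusted p = 0.00286). The number fell to 214 without LNA replicate 1, 276 without LNA replicate 3, 243 and 255 without control replicates 1 and 2, and 251, 275 and 278 without wild-type cord replicates 1, 3 and 4, and it was 958 without knockout replicate 7 and the library labelled knockout replicate 9. The materials also differ in cell make-up and time without miR-146a, and may differ in genetic background. Their libraries differ in RNA content, with Rn7sk at 0.5176% to 1.245% of counts in cords and 0.0001% to 0.0003% in cultures.

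The number of genes shared by both comparisons was close to what independent lists give. Directions were set against an expected number only for genes moving the same way, and were not tested. Of 17760 genes tested in both, 0 passed in both with edgeR, and 77 had an unadjusted p below 0.01 in both, where 69.8 would be expected (Fisher's exact p = 0.363), of which 14 were higher in both (9.48 expected), 16 lower in both (27.3 expected) and 47 opposite. The overlap of all DESeq2 calls between materials was not counted. Across genes, which are not independent replicates, fold changes had a Pearson r of 0.0498 and a Spearman rho of −0.00822. Pearson r was 0.0159 without knockout replicate 7, 0.0833 without the library labelled knockout replicate 9, and 0.0171 and 0.0292 without LNA replicates 1 and 2. Genes among those with the smallest p in both were Il1r1 (1.84 in cords, 1.01 in cultures), the kinase Hipk1 (0.31, −0.28), Plekhd1 (−0.38, 0.97) and the septin Sept4 (−0.35, 0.31). With edgeR each had passed in the cultures and not in the cords (adjusted p = 0.292). With DESeq2 each passed in both, the adjusted p in cords being 3.67e-05, 0.0101, 0.0278 and 0.0261.

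Seed sites for miR-146a-5p, the sequence AGTTCTC in 3' UTRs, were compared next, since loss of a microRNA is expected to raise transcripts that carry them. In cords, the median log2 fold change of 1932 genes with a site exceeded that of 13700 genes without by 0.0247, which camera did not call, and 26 of 200 control words gave a difference as high. It was 0.0117 without wild-type replicate 4 and 0.016 without the library labelled knockout replicate 9, and among genes at 5 CPM or more it was 0.0291, which camera called at the 0.05 threshold. In cultures, 1827 genes with a site lay below 12510 genes without, by −0.0508, which camera called at the 0.05 threshold, with a median of −0.0479 over the control words, of which 142 were as high or higher. With 3' UTR length, A+U share and expression in a linear model, the coefficient of a site in cultures was −0.027 (SE 0.00888), against a median of −0.00715 over the control words, of which 4 of 200 were as low or lower. In cords it was 0.0151 (SE 0.0138), and 30 of 200 were as high or higher.

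Genes around the targeted locus were compared with all others. Within 5 Mb of Mir146, edgeR called 0 of 41 genes in cords, with 6 at an unadjusted p below 0.05, and 5 of 43 in cultures, or 11.6% against 8.55% elsewhere (Fisher's exact p = 0.413). The count in cultures was 1 without control replicate 2. Without the library labelled knockout replicate 9, 1 gene of this window, Pttg1, was called in cords. The other gene called in that fit, Col23a1 (chromosome 11, 51289920 to 51583918), lies outside this window but within 10 Mb of Mir146. Col23a1 stood at 26.55 normalised CPM in the library labelled knockout replicate 9. It stood at 50.08 to 59.93 in the other knockouts and at 38.2 ± 4.00 in wild-type cords.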

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

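Tests chosen only after the result was seen were those on Xist, on knockout replicate 7, on blood, on the depth behind Sod1, on control words in the seed-site model, both tests on Pttg1 and the permutation of list scores; the other tests were fixed before. A Dixon-type rule, which asks whether 1 library lies far from the rest of its group, was applied to 110 groups of 4 to 10 cord libraries. It set 20 apart. Chance sets about 1 in 20 independent groups apart, but these share libraries and include genes chosen because 1 library stood out, so the 20 are not weighed against that share. Normalised CPM is given unless CPM is named.

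Knockout replicate 7 lay far above the other knockouts for Alas2 (22.96), Slc4a1 (12.8), Dchs1 (49.56), Itgax (59.83), Mx1 (2.421), Ccl2 (5.054), Tlr4 (9.284) and Il1r1 (20.83), and for the scores of miR-146a targets (0.6785), skeletal muscle (7.67) and meningeal fibroblasts (2.716), with Acta1 at 2436 CPM and Col1a1 at 1092 CPM. The library labelled knockout replicate 9 stood apart for Sod1 (1947), Pttg1 (13.04) and Col23a1 (26.55). Knockout replicate 4 was low for Sc5d (67.33) and the cholesterol synthesis score (−0.5686). Among wild-type cords, replicate 1 was high for Slc4a1 (0.3418) and the skeletal muscle score (0.2572).

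The knockout effect in cords and the LNA effect in cultures differed by an interaction test in edgeR for 29 of 85 named genes. The named genes include those picked for the largest LNA effects or for this difference, so that share is set by the choice. Over all genes the test called 423 of 24152, and 3 of 50 splits of the libraries gave as many (highest other 528). The 7 other splits that keep the real grouping of the cultures gave 231 to 528 genes and so carry the LNA effect, while the 42 that break it gave 0 to 7, so these splits test only the cord grouping. The knockout effect minus the LNA effect, on the log2 scale, was positive for Htr1a (7.204, a fitted value that depends on the prior count, since 1 group had 0 counts), Mylk (1.827), Sytl5 (1.563), Chrna2 (1.542), Aff2 (1.249), Col25a1 (1.173), Zfp804b (1.173), Synpr (1.144), Cacna2d3 (1.111), Sorcs2 (1.001), Gad1 (0.9152), Mfhas1 (0.8666), Dcc (0.8032), Dchs1 (0.6816), Nos1 (0.623), Hipk1 (0.6136), Nlgn1 (0.5046) and Robo1 (0.3811). It was negative for Ttr (−3.644), Chodl (−2.739), Gsta4 (−2.131), Bcas1 (−1.858), Myl9 (−1.658), Npepl1 (−1.545), Hist1h4i (−1.506), Rnf135 (−1.424), Plekhd1 (−1.318), Emc1 (−0.8789) and Sept4 (−0.6409).

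Genes that fell after the miR-146a LNA span long stretches of the genome. The median span was 111 kb for genes that fell and 18.6 kb for genes that rose, against 25.4 kb over all genes, and among the 3603 genes with the longest spans 779 fell and 53 rose. Bias from transcript length or GC content as the whole cause is argued against, since the slope of fold change on log2 span was −0.033 (SE 0.002) with both in the model. Release of seed-site targets would raise those targets, so it could not itself lower them whatever the values. The values on sites ask only whether genes with a site were higher. Genes with a site were lower by −0.0508, which alone decides nothing, since 200 control words gave a median of −0.0479 and 142 were as high or higher. With 3' UTR length, A+U share and expression in the model the coefficient was −0.027 (SE 0.00888), and 4 of 200 control words were as low or lower. Genomic span was not in that model, so a release hidden by the trend with span is not excluded. Pairing of the LNA with transcripts holding 10-base stretches of the miR-146a sequence stays open (−0.0367, SE 0.0207, beyond reversed stretches). A lower rate of transcript elongation or more intron-bearing RNA in the controls may also give such a slope and was not tested.

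Immune and glial lists were higher in knockout cords by camera with a preset correlation. With an estimated correlation 0 lists are called (3177 single genes had an unadjusted p below 0.05 with edgeR). Fry calls 1, red blood cells (adjusted p = 0.014), and no immune or glial list. By permuted scores 0 are called, the smallest adjusted p being 0.0546, also for red blood cells. Muscle and connective tissue carried into knockout replicate 7 is argued against as the whole cause, since the disease-associated microglia score difference was 1.27 (SE 0.365) without it, against 1.46 with it and a bound of 0.364, below which it would be taken as the cause (exact permutation p = 0.0364, 8 against 4). Unequal sexes as the whole cause are argued against by the same bound, since among libraries with Xist above 100 CPM the difference was 1.48 (SE 0.455; exact permutation p = 0.0667, 7 against 3). Both differences lie over 2 SE above the bound, a rule set after the values were seen in place of an exact p below 0.05, which the test on sexes misses. Blood left in the cords stays open, since both tests of it, the score differences of reactive astrocytes (1.25, exact permutation p = 0.014) and homeostatic microglia (0.678, exact permutation p = 0.0769), restate lists of the pattern. A response to loss of miR-146a may explain these lists, as may blood, age, litter or housing, which the labels do not give.

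The library labelled knockout replicate 9 had Pttg1 at the wild-type level and Sod1 8.05 times the mean of the other knockouts. A swap with a wild-type cord is argued against, since the lowest Pttg1 among wild-type cords was 14.9 and no partner was out of place. A wrong label, or a swap with a sample outside the series, stays open: on a scale from 0 at the wild-type mean to 1 at the mean of the other knockouts, over 100 genes, that library lay at 0.385, but knockout replicate 2, with Pttg1 at 1.53, lay at 0.188. For Sod1, gain of the surrounding chromosome segment is argued against by a median log2 ratio of 0.158 over 13 neighbours (−0.687 to 0.592), and depth or scaling by a 99th percentile of 0.77 among genes at its level, against 3.01 for Sod1. Over all tested genes, 82 had a larger ratio than Sod1, so that library differed from the other knockouts in more than Sod1. It also had a count in 32994 genes, the most of any library. What lies behind these wider differences was not tested. A Sod1 transgene or another change at Sod1 itself may explain the Sod1 value. A regulatory effect of the deletion on Pttg1 or of its flanking strain sequence may explain Pttg1 in the other knockouts. None of these was tested.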

How the results depend on the processing

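The alternatives without both libraries that stand apart, those among libraries with Xist above 100 CPM and the permuted scores were chosen after seeing the data; the others were fixed before. In simulated cords, whose groups had equal dispersion, edgeR recovered 70% of 2-fold changes. Where a result below was not kept, the cause was not tested, except that leaving out a library or testing fewer genes changes what can be called. DESeq2 was also set to replace outlying counts among the knockout cords, so its cord values need not rest on every count as deposited. In cords, 0 genes changed in the main test, against 348 with DESeq2, 3 with limma, 2 with sva, 8 without both libraries that stand apart, 1 among libraries with Xist above 100 CPM, and 0 to 2 on leaving out 1 library. Of 39 named cord genes, 31 gained a call under at least 1 alternative. In cultures, 1635 genes changed, against 388 with a fold threshold, 2141 with DESeq2, 2253 with limma, 2261 with no filter, and 778 to 1985 on leaving out 1 library. Of 52 named genes called in cultures, 34 kept their call throughout and 0 changed sign. All 18 that lost it did so on leaving out 1 library: Aff2, Atp5h, Cbln4, Col25a1, Cox5b, Ddx58, Gad2, Ghsr, Il1r1, Mcm6, Nos1, Nova1, Plekhd1, Sept4, Slc6a5, Sytl5, Top2a and Vnn1. With the replicate number as a block, 1793 genes were called; same-numbered cultures share only a number, with correlations of 0.00978, −0.0501 and 0.00568. Lists called in cords numbered 25, against 0 with an estimated correlation, 1 with fry (red blood cells) and 0 by permuted scores, and 18 kept their call on leaving out any 1 library. In cultures 12 lists were called, against 0, 5 and 0, and 10 were kept on leaving out any 1 library. The difference covered 423 genes, against 892 with DESeq2, 958 without both libraries, and 214 to 621 on leaving out 1 library, and its 5 named genes were kept throughout. Genes past the threshold in both comparisons, whatever their direction, numbered 0, against 77 at an unadjusted p below 0.01 (14 higher in both, 16 lower in both, 47 opposite) and 1 without both libraries. The correlation was −0.0121 at 5 CPM or more and 0.0159 to 0.0833 on leaving out 1 library. The seed-site difference in cords (0.0247) was 0.0291 at 5 CPM or more, where camera called it, 0.0127 without both libraries and 0.0117 to 0.0284 on leaving out 1 library. Genes called near Mir146 numbered 0 to 1 in cords and 1 to 6 in cultures on leaving out 1 library.

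Signs reversed as follows. With sva, Traf6 was −0.0243 and Irak1 −0.0133 in cords. Sod1 in cords was −0.138 with DESeq2, −0.0252 with limma, −0.0998 with sva, −0.0979 without both libraries, −0.163 among libraries with Xist above 100 CPM and −0.152 to 0.787 on leaving out 1 library. Differences of list scores in cords became 0.0212 for ALS genes by library size alone and, without both libraries, 0.0211 for spinal interneurons, −0.0761 for skeletal muscle and −0.0197 for oligodendrocyte precursors. In cultures, library size alone gave 0.0299 for ALS genes, 0.0440 for the circadian clock, 0.0150 for neural progenitors and 0.0358 for the unfolded protein response. On leaving out 1 cord library, these differences ran from −0.0662 to 0.00280 for heat shock, −0.0175 to 0.00256 for ALS genes, −0.115 to 1.08 for skeletal muscle, −0.00523 to 0.0903 for neural progenitors and −0.0145 to 0.0560 for oligodendrocyte precursors. On leaving out 1 culture, they ran from −0.147 to 0.0329 for immediate early genes, −0.0383 to 0.0268 for the circadian clock, −0.125 to 0.169 for oligodendrocytes, −0.0357 to 0.0565 for miR-146a targets, −0.0593 to 0.165 for astrocytes, −0.141 to 0.00820 for neural progenitors, −0.0217 to 0.0266 for NF-kB, −0.0414 to 0.0189 for the unfolded protein response and −0.00258 to 0.287 for skeletal muscle.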

Other observations

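The counts of splits were fixed before the data were examined, and their reading by the grouping of the cultures was chosen after. List values on leaving out 1 library are differences of list scores. Homeostatic microglia genes were all positive in knockout cords, with a median log2 fold change of 0.91 over 20 genes (camera adjusted p = 4.41e-06, adjusted p = 0.462 with an estimated correlation). Lists higher in the same way were the glucocorticoid response (median 0.66, adjusted p = 2.82e-07, adjusted p = 0.339 with an estimated correlation), the cell cycle (0.61, adjusted p = 3.65e-05, adjusted p = 0.462 with an estimated correlation), ependymal cells (0.41, adjusted p = 0.000437, adjusted p = 0.339 with an estimated correlation), axon injury (0.39, adjusted p = 0.00129, adjusted p = 0.462 with an estimated correlation) and lymphocytes (1.48, adjusted p = 0.00521, adjusted p = 0.462 with an estimated correlation). Immediate early genes (0.31, adjusted p = 0.0129, adjusted p = 0.468 with an estimated correlation), endothelium (0.28, adjusted p = 0.0304, adjusted p = 0.503 with an estimated correlation) and pericytes (0.21, adjusted p = 0.0448, adjusted p = 0.468 with an estimated correlation) followed. Lymphocytes lost the call without knockout replicate 7 (0.58, against 0.826 with all). Immediate early genes lost it without wild-type replicates 1 (0.224) and 2 (0.245). Endothelium lost it without wild-type replicates 1 (0.29), 2 (0.291) and 3 (0.303) and knockout replicates 4 (0.284), 6 (0.294) and 7 (0.249). Pericytes lost it without wild-type replicates 1 (0.235), 2 (0.208) and 3 (0.184) and knockout replicates 1 (0.218), 2 (0.223), 4 (0.21) and 7 (0.0895).

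Lower in knockout cords were pan-neuronal genes (median −0.16, adjusted p = 8.43e-05, adjusted p = 0.339 with an estimated correlation), synapse genes (−0.07, adjusted p = 0.00317, adjusted p = 0.503 with an estimated correlation), myelin genes (−0.14, adjusted p = 0.00521, adjusted p = 0.477 with an estimated correlation) and mitochondrially encoded genes (−0.10, adjusted p = 0.0304, adjusted p = 0.561 with an estimated correlation). Heat shock genes had a median of −0.10 and a mean of 0.01 (adjusted p = 0.0138, adjusted p = 0.462 with an estimated correlation). Synapse genes went from −0.0693 to −0.0286 without knockout replicate 7. Myelin genes (−0.145) lost the call without wild-type replicate 2 (−0.0789) and had −0.221 without wild-type replicate 4. Mitochondrially encoded genes (−0.0764) lost it without wild-type replicates 1 (−0.0522) and 3 (−0.0588), knockout replicates 1 (−0.0635) and 3 (−0.0542) and the library labelled knockout replicate 9 (−0.0552). Heat shock genes (−0.0333) lost it without wild-type replicate 3 (−0.00959), and had −0.0553 without wild-type replicate 2, −0.0541, −0.0662 and −0.014 without knockout replicates 5, 7 and 8, and 0.0028 without the library labelled knockout replicate 9. Fibroblast, interneuron, ALS, Schwann cell, neurotrophic, p53, axon guidance, skeletal muscle, neural progenitor, sensory ganglion, astrocyte, unfolded protein response, circadian and oligodendrocyte precursor lists were not called, with adjusted p from 0.091 to 0.872. With the preset correlation, interneurons gained a call without wild-type replicate 1 (−0.0838), knockout replicate 2 (−0.0785) and knockout replicate 3 (−0.0758). Schwann cells gained one without wild-type replicate 4 (1.11), and fibroblasts (0.603) and ALS genes (−0.0127) without the library labelled knockout replicate 9. With an estimated correlation, neither fibroblasts nor ALS genes were called without that library. Among the lists not called with all libraries, median, mean and test differed in sign for ALS genes, neural progenitors and oligodendrocyte precursors.

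In the cultures, 6 of 20 pan-neuronal genes fell, both over all genes and adjusted over the list alone (median −0.10, camera adjusted p = 0.00331, adjusted p = 0.399 with an estimated correlation). Of 20 axon injury genes, 8 fell, and adjusted over the list alone 10 fell and 2 rose (median −0.20, camera adjusted p = 0.00468, adjusted p = 0.559 with an estimated correlation). Complement genes (0.31, adjusted p = 0.00335, adjusted p = 0.399 with an estimated correlation), pluripotency genes (0.48, adjusted p = 0.0263, adjusted p = 0.399 with an estimated correlation) and fibroblast genes (0.44, adjusted p = 0.035, adjusted p = 0.449 with an estimated correlation) were higher. Complement genes went from 0.265 to 0.156 without control replicate 3, and pluripotency genes lost the call without LNA replicate 1 (0.586, against 0.721). Fibroblast genes (0.389) lost it without LNA replicates 1 (0.236) and 2 (0.294) and control replicate 3 (0.217), and had 0.637 without LNA replicate 3. A call was gained by immediate early genes without LNA replicate 1 (−0.147) and control replicate 1 (−0.134), by mitochondrially encoded genes without LNA replicates 1 (0.403) and 2 (0.435), and by disease-associated microglia genes without control replicate 3 (0.232). With all libraries the other 25 lists were not called, with adjusted p from 0.0543 to 0.977, and median, mean and test differed in sign for the circadian clock, oligodendrocyte precursors, neurotrophic support, Schwann cells, astrocytes, the unfolded protein response, NF-kB and miR-146a targets.

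Other splits of the same libraries were counted, the real split included. For cords, 100 of 715 possible splits were drawn. For the number of genes called by edgeR the splits decide nothing, since the real count was 0 and any split gives as many (100 of 100, highest other 1). The 348 genes called by DESeq2 were not tested by splits. Chance is not excluded for the 3177 genes at an unadjusted p below 0.05 (8 of 100 splits, highest other 5575). What sets those other splits apart was not tested. For the 25 lists called by camera, 2 of 100 splits gave as many (highest other 26, median 14), a share below the 0.05 of the rule used. Camera with a preset correlation thus calls many lists in arbitrary splits. Permuted scores call 0 lists after adjustment, so chance is not excluded for any single list. The seed-site difference in cords (0.0247) was matched in 13 of 100 splits (highest other 0.0352) and the correlation between comparisons (0.0498) in 55 of 100 (highest other 0.152), so chance is not excluded for either. For the 423 genes that differ between materials, 3 of 50 splits gave as many (highest other 528), all of which keep the real grouping of the cultures, so chance is not excluded for the cord grouping behind that count. The 6 cultures have 10 splits, too few for a share under 0.05: the real split alone, 1 of 10, gave 1635 genes (highest other 0), 12 lists (highest other 7) and a seed-site difference of 0.0508 in size (highest other 0.0326).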
